A study of Mus musculus with 2 samples.

How the data were processed

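Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out by the submitters on the hindbrain of mouse embryos at embryonic day 13.5, with an antibody against histone H3 acetylated at lysine 9 (H3K9ac), a mark found at active promoters and, more weakly, at active enhancers. Per the labels, the embryos were of strain B6NCrl, the tissue was pooled from males and females, and there were 2 biological replicates of 1 group. There was therefore no second condition to compare, and each replicate is 1 library. The labels name a possible control experiment, which was not used here.

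The deposited files were 4 peak lists in narrowPeak format on assembly mm10. Per the file descriptions deposited with the samples, 1 list was called on each replicate's alignments, 1 was called on both replicates' alignments together (the pooled list), and 1 (the replicated list) was derived from the other 3. Each peak has a ratio, the enrichment (fold) of ChIP signal over background, as the authors deposited it, and it is used here only to describe, rank or filter peaks within a list. Each peak also has a -log10 p and a -log10 q as the authors deposited them, and the position of its summit as a distance from the peak's start, likewise from the deposited files. The lowest -log10 p in the deposited lists corresponds to a p of 0.01. The peak caller, its version, the aligner, the filters and the overlap rule behind the replicated list are not given in the sources used here. Every row of the replicated list was a row of the pooled list. The lists hold no read counts, so the depth of each replicate is unknown, no interval that needs depth is given, and no count model was fitted.

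Gene models were taken from the basic annotation of GENCODE release M21 on GRCm38, the assembly that mm10 names, and sequence from the GRCm38.p6 reference. The last peak on each chromosome lay inside the length of the reference chromosome. Analyses used chromosomes 1 to 19, X and Y, and the 21851 protein-coding genes there with at least 1 protein-coding transcript. A gene was called marked when a replicated peak overlapped the window of 1000 bp to either side of any of its 41438 transcription start sites (TSSs) by at least 1 bp. The strength of a marked promoter was the highest enrichment among the replicated peaks that overlapped that window, even where a wide peak had its summit outside it. Breadth was the greatest length covered by replicated peaks within 5 kb of a TSS, out of 10001 bp. A distal peak lay over 2.5 kb from every annotated TSS of any gene and was assigned to the protein-coding gene with the TSS nearest to its summit. Promoter CpG content was the observed over expected CpG ratio within 500 bp of the TSS, the highest over a gene's TSSs, with a boundary of 0.6 between CpG-rich and CpG-poor. A window around a TSS can also be reached by a peak at the promoter of a neighbouring gene, so for each named gene it was checked whether the peak also overlapped the promoter window of another protein-coding gene.

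The overlap of the replicates' lists and the share of replicated peaks at promoters were tested against 1000 circular shifts of the peaks along each chromosome (one-sided permutation tests). Replicated shares near and away from TSSs were compared with Fisher's exact test and with a permutation of blocks of 1 Mb, drawn 1000 times. Marking of each of 26 gene lists was compared with that of all other protein-coding genes by a two-sided Fisher's exact test. Strength and breadth were compared by a two-sided permutation test (100000 resamples) of the list's median percentile among all marked genes, for lists with at least 3 marked members. Distal peaks per gene were compared with random genes of the same decile of territory length, the stretch of chromosome nearest to the gene's TSSs (two-sided permutation test, 100000 resamples). All p-values over lists were Benjamini-Hochberg adjusted within each family. The smallest p that the shifts can give is 0.001, and the smallest that the two-sided resamples can give is 2e-05. Genes and peaks are not independent replicates, so these p-values describe where the mark lay in this pair of libraries and not the spread between animals. For the marking of genes and lists, Hox coverage and the share of peaks at promoters, the spread between replicates is given by repeating the count on each replicate's own list. The CpG classes and the CpG-matched marking were not repeated in this way.

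The gene lists, the tests and most alternatives were fixed before the data were examined. Apart from the olfactory and vomeronasal receptor families, taken by symbol, the lists held 437 gene names, of which 9 stood in more than 1 list (Aldh1a1, Cdon, Cspg4, Gli2, Otx2, Pax7, Plp1, Sox10 and Ttr), and 1, in the erythroid list, had no match in the annotation. The lists covered Hox groups 1 to 5 and 8 to 13, hindbrain patterning, rhombic lip and cerebellum, brainstem neuron regulators, neural progenitors, pan-neuronal genes, neurotransmitter genes, glia, forebrain regulators, midbrain and dopaminergic genes, the Sonic hedgehog pathway, retinoic acid, cell cycle, housekeeping, erythroid, endothelial, microglia and macrophages, mesenchyme with meninges and mural cells, choroid plexus, neural crest with Schwann cells, skeletal muscle, liver, germline and the 2 receptor families. The genes named were the 10 with the broadest mark (with ties), the 10 with the strongest, the 5 with the most distal peaks, and, in each list, the 3 strongest and 2 broadest marked members and the unmarked members where these were 5 or fewer, otherwise the first 3 in the order of the list. Genes named outside this rule are identified where they appear. Unmarked genes had no replicated peak in the window, but could have a peak in a replicate's own list. Of those named, Dbx1, Th, Mag, Foxg1, Nkx2-1, Cdh5, Cx3cr1, Dcn, Myf6, Apoa2 and Olfr1414 had one in replicate 1 alone. Hnf1b, Foxa2, Acta2 and Apoa1 had one in replicate 2 alone, and Tbr1 had one in each.

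Alternatives were a promoter window of 500 or 2000 bp, a -log10 q of at least 2, the pooled list or each replicate's own list in place of the replicated list, matching on decile of promoter CpG, 1 TSS per gene, other windows, distances and CpG boundaries, and lists of equal length. A further one, chosen after seeing the data, kept only the replicated peaks that were covered to at least 50% (of either interval) by a peak of each replicate. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1. The list tests of marking, strength and distal peaks and the overlap of the replicates were tested on simulated data, and the other statistics were not. Among 100 random lists of 25 genes drawn from 21851, the marking test gave an unadjusted p below 0.05 in 6.0% and, for lists with 95% of members marked against 65%, in 97.0%. For lists with 90% of members marked it did so in 75.0%. Where the simulated mark followed CpG content alone and the lists held CpG-rich promoters, the unmatched test gave such a p in 97.0% of lists and the CpG-matched test in 2.0%. The strength test gave such a p in 8.0% of random lists among 14316 marked genes and in 89.0% of lists with doubled values. The distal test gave 5.0% for random lists among 21851 genes, 14.0% for lists with a doubled mean and 50.0% for lists with a tripled one.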

Results

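H3K9ac was profiled in the hindbrain of mouse embryos at embryonic day 13.5, the part of the neural tube that forms the cerebellum, pons and medulla. The series held 2 biological replicates of this 1 tissue and stage. The lists held 105833 peaks for replicate 1, 92751 for replicate 2, 121252 for the pooled alignments and 52100 in the replicated list. On chromosomes 1 to 19, X and Y the replicated list had 52089 peaks with a median width of 622 bp, which covered 50.4 Mb. The median enrichment of these peaks was 3.83, and 99.1% of them had a -log10 q of at least 2, against 70.3% of replicate 1's peaks and 66.6% of replicate 2's. Read depth is unknown, as the lists hold no counts.

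The first question was how far the replicates marked the same places. Strong peaks were shared throughout and weak ones mostly were not. Of replicate 1's peaks, 45.5% overlapped a peak of replicate 2 by at least 1 bp, and of replicate 2's peaks 54.4% overlapped one of replicate 1. After circular shifts of replicate 2's peaks the latter share averaged 4.37% and never exceeded 5.51% (permutation p = 0.001, the smallest 1000 shifts can give). Replicate 2's share was 33.7% when the overlap had to reach 50% of both peaks, and 92.7% among the 10000 strongest peaks of each replicate. In the strongest decile by -log10 p, 100% of each replicate's peaks were shared, while in the weakest decile 20.1% of replicate 1's and 24.9% of replicate 2's were. Across the 43716 pooled peaks that met a peak of each replicate, the enrichments in the replicates were correlated across peaks with a Spearman's rho of 0.816. Peaks are not independent replicates, so no p is given for it.

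**Figure D1:**
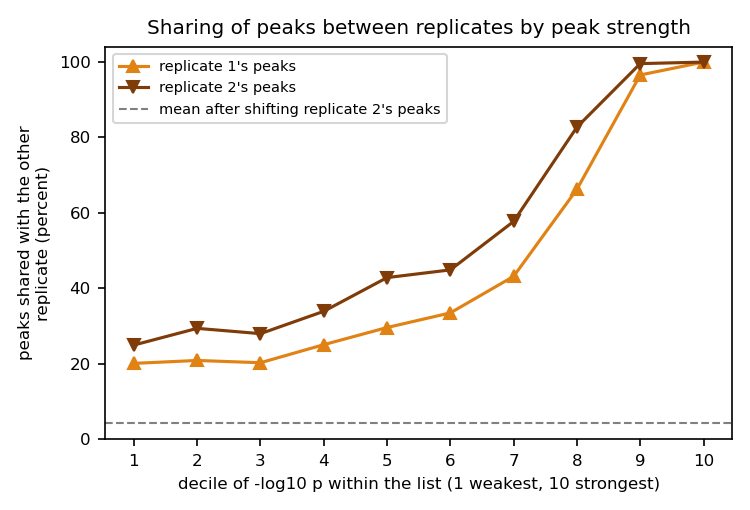
Percent of each replicate's peaks that overlap a peak of the other replicate (vertical axis) by decile of -log10 p within the replicate's own list (horizontal axis, 1 weakest to 10 strongest). The share rises from 20.1% and 24.9% in the weakest decile to 100% in the strongest, and the dashed line marks the 4.37% found after shifting replicate 2's peaks.

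Pooled peaks at promoters were replicated more often than those elsewhere, although most replicated peaks lay away from promoters. Of the pooled peaks within 1 kb of a protein-coding TSS, 83.9% (17829 of 21250) were in the replicated list, against 34.3% (34260 of 99988) of those farther away, an odds ratio of 10 (95% interval 9.62 to 10.4). This interval and those of the other odds ratios take peaks or genes as independent and are too narrow. The permutation of 1-Mb blocks gave p = 0.001, the smallest it can give. Within quartiles of enrichment in the pooled list the difference was 2.23 to 8.99 percentage points, against 49.6 over all peaks. The odds ratio was 1.66, 1.17 and 1.44 in the lower 3 quartiles and 8.79 (95% interval 6.85 to 11.3) in the strongest, where 99.6% and 96.3% of peaks were replicated. Promoters of protein-coding genes were overlapped by 34.2% of replicated peaks, against a mean of 3.26% and a maximum of 3.99% after circular shifts (permutation p = 0.001, the smallest they can give). The share was lower in the longer lists, 17.5% in the pooled list, 23.2% without replicate 1 and 20.6% without replicate 2. By the position of the summit, 32.3% of replicated peaks lay at such promoters, which make up 2.03% of the genome. A further 39.9% lay in introns, close to the introns' 40.3% of the genome, 7.19% in exons, 4.09% at promoters of other genes, and 16.4% between genes, where 52.4% of the genome lies. Median enrichment was 12.7 at protein-coding promoters, 3.30 in introns and 3.44 between genes.

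Of 21851 protein-coding genes, 14340 (65.6%) had a marked promoter. The mark followed CpG content closely: 97.8% of CpG-rich promoters (10815 of 11063) and 32.7% of CpG-poor ones (3525 of 10788) were marked, an odds ratio of 89.9 (95% interval 78.7 to 103). Across deciles of CpG content the marked share rose from 2.33% to 99.1%, and the median enrichment of marked promoters from 3.72 in the lowest decile to 21.3 in the highest. Replicate 1's own list marked 14832 genes and replicate 2's 14604. Both marked 14284, replicate 1 alone 548 and replicate 2 alone 320 (exact McNemar test, two-sided p = 9.25e-15, which compares these libraries and not conditions). With equal numbers of peaks these were 464 and 364 (exact p = 0.000573). The genes marked in 1 replicate alone had weak peaks, with a median enrichment of 3.05 in replicate 1's list and 2.89 in replicate 2's, against 15 and 12.7 for the genes that both marked.

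The Hox genes, which give segments along the body axis their identity, split by their place in the cluster. All 15 genes of paralog groups 1 to 5, the groups at the 3' ends of the clusters that include the hindbrain Hox genes, were marked in the replicated list and in each replicate's own list. Of the 19 genes of groups 8 to 13, which act in the trunk, limbs and tail, 3 were marked (Hoxb8, Hoxb9 and Hoxd8), with 4 marked in replicate 1's list and 6 in replicate 2's. Both lists differed from other protein-coding genes (Fisher's exact test, adjusted p = 0.00475 and 4.91e-05). Against genes matched on promoter CpG content, 94.0% of which would be marked for groups 8 to 13, the low share of those groups stayed apart (permutation, adjusted p = 0.000104). The full share of groups 1 to 5 then stood against 83.1% and no longer passed (permutation, adjusted p = 0.24). Hox genes are neighbours that share peaks, so their number overstates the independent evidence.

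Within each cluster the peaks lay mostly over the lower group numbers, and not only over groups 1 to 5. In groups 6 and 7, Hoxa6 (enrichment 10.9), Hoxa7 (5.45), Hoxb6 (29.7), Hoxb7 (15.2) and Hoxc6 (5.64) were marked, also in each replicate's own list. Hoxa6, Hoxa7, Hoxb7 and Hoxc6 are named here outside the rule. In HoxA (chromosome 6, 52155590 to 52260880) replicated peaks covered 93.1% of the span of groups 1 to 5 and 0% of that of groups 8 to 13. The former span reaches the end of the long annotated Hoxa3 and so also holds Hoxa6. In HoxB (chromosome 11, 96194316 to 96368256) the shares were 81.6% and 11.1%, and a single peak of 55938 bp (96291589 to 96347526) spanned the promoters of Hoxb3, Hoxb4, Hoxb5 and Hoxb6. Most of the HoxB span of groups 8 to 13 is the stretch without Hox genes between Hoxb13 (end 96197447) and Hoxb9 (start 96271457). Its replicated peaks all lay from 96271417 on, over most of the part that holds Hoxb9 and Hoxb8, so the 11.1% understates their coverage. In HoxD (chromosome 2, 74668310 to 74765142) they were 55.9% and 2.06%. In HoxC (chromosome 15, 102921103 to 103036852) they were 30.8% and 0.436%, where the spans overlap because of the long annotated span of Hoxc5. The HoxC span of groups 1 to 5 also holds Hoxc6. The replicates' own lists gave 91.1% and 84.6% for groups 1 to 5 of HoxA, 82.0% and 79.6% for HoxB, 28.7% and 27.7% for HoxC, and 54.7% and 52.0% for HoxD. Hoxb2 (enrichment 36.1), Hoxa2 (33.7), a gene needed for the identity of the second rhombomere and second branchial arch, and Hoxb3 (29.7) had the highest values of groups 1 to 5. Hoxb4 and Hoxb5 tied with Hoxb3 through their shared peak, as did Hoxb6. The summit of that peak lay 1761 bp from the nearest coding TSS, at Hoxb3, outside every promoter window. Its 29.7 therefore does not measure strength at these promoters, and in replicate 1's own list Hoxb6 had 16.4. Hoxb8, whose peak also covered the promoter of Hoxb7, reached 15.2, Hoxb9 5.16 and Hoxd8 4.13. Hoxc8, Hoxa9 and Hoxc9 were among the unmarked members of groups 8 to 13.

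**Figure D2:**
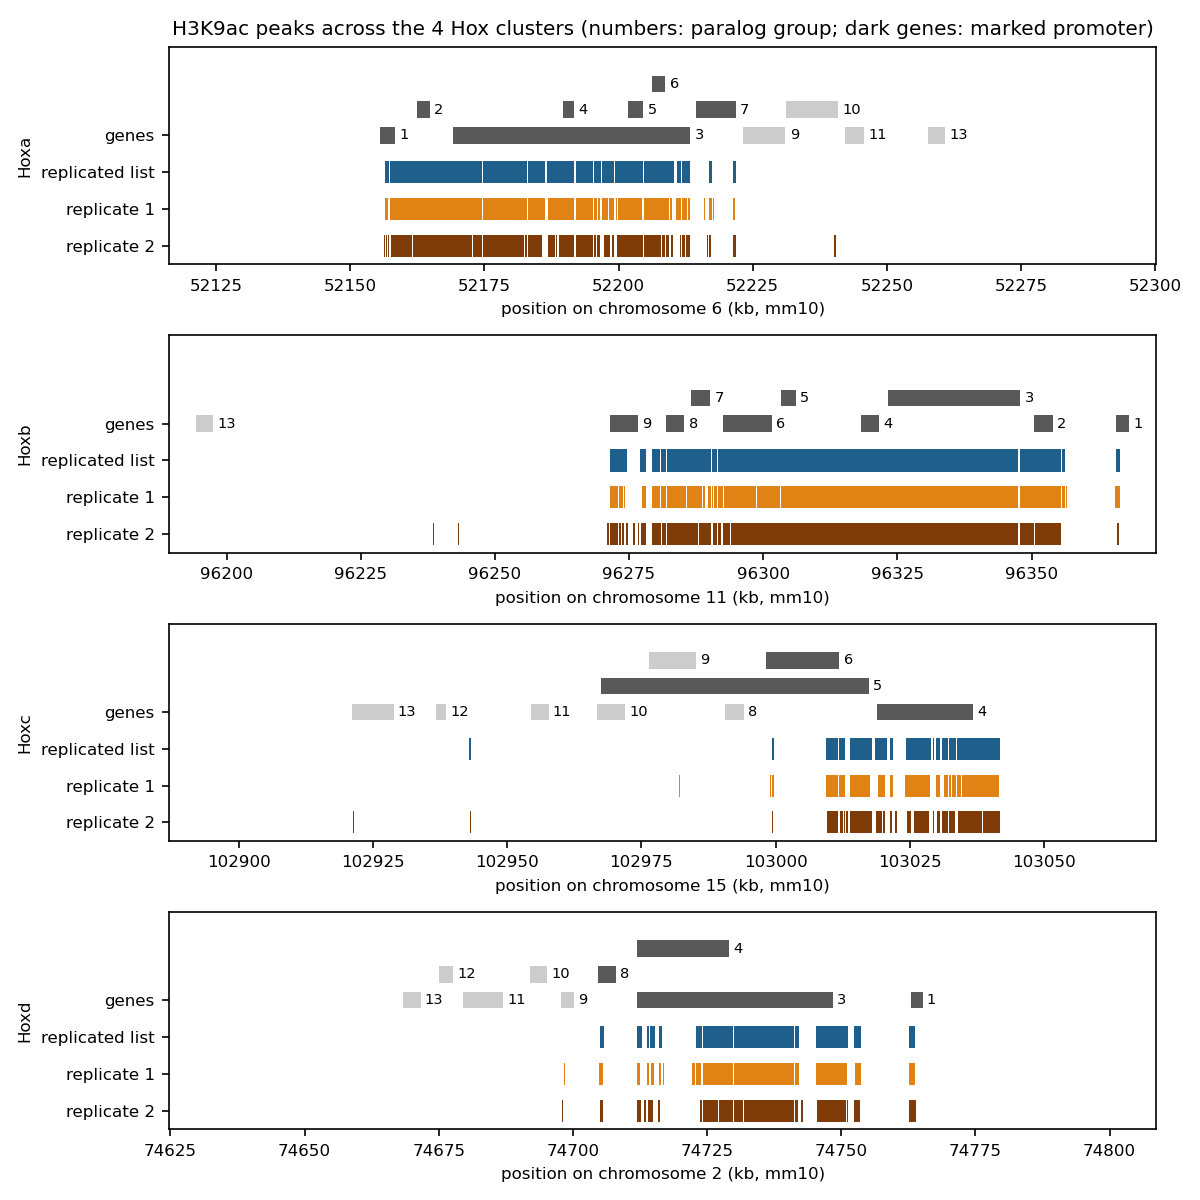
Maps of the 4 Hox clusters on mm10 (horizontal axes in kb, same scale), with genes numbered by paralog group and drawn dark where the promoter was marked in the replicated list, over the peaks of the replicated list and of each replicate. Peaks cover 93.1%, 81.6%, 30.8% and 55.9% of the spans of groups 1 to 5 in HoxA, HoxB, HoxC and HoxD, and 0% to 11.1% of the spans of groups 8 to 13. The 11.1% is that of HoxB, where most of the span is the stretch between Hoxb13 and Hoxb9.

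Regulators of hindbrain development carried the mark almost without exception. Of 25 hindbrain patterning genes, which set up the rhombomeres and the midbrain-hindbrain boundary, 23 were marked, led by Meis1 (enrichment 36.8) and Meis2 (33.7), cofactors of Hox proteins, and Efnb2 (31.6), while Pax5 and Hnf1b were not. Of 25 rhombic lip and cerebellar genes 24 were marked, with Nfib (30.8), Cdon (27.7) and Zic1 (24.2) the strongest and Tbr1 unmarked. Of 27 regulators of brainstem neuron types 26 were marked, with Lbx1 (17.6), Lmx1b (16.2) and Pou4f1 (11.7) the strongest and Dbx1 unmarked. Neural progenitor genes were marked in 19 of 20 cases, led by Msi1 (42.9), Id4 (33.3) and the Notch ligand Dll1 (25.9), with Nr2e1 unmarked. All 13 Sonic hedgehog pathway genes were marked, with Cdon, Ptch1 (23.5), the receptor, and Gas1 (21.2) the strongest. The replicates' own lists marked 23 and 23 patterning, 25 and 24 rhombic lip, 27 and 25 brainstem, 19 and 19 progenitor and 13 and 13 hedgehog genes. The adjusted p against all other genes was 0.00854 for hindbrain patterning, 0.00121 for the rhombic lip list, 0.000922 for brainstem regulators, 0.0075 for progenitors and 0.0103 for the hedgehog pathway (Fisher's exact test). None of these 5 differences passed once genes were matched on promoter CpG content: matched genes were marked in 92.0%, 96.3%, 96.0%, 93.2% and 94.6% of cases, with an adjusted p of 1.0 for each list. With a promoter window of 500 bp the hedgehog pathway did not pass either (exact test, adjusted p = 0.0639).

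Pan-neuronal genes were marked beyond what their CpG content gave. All 25 were marked in the replicated list and in each replicate's own list (Fisher's exact test, adjusted p = 0.000193), against 76.9% of CpG-matched genes (permutation, adjusted p = 0.000104). Tubb3 (enrichment 35.1), the neuronal beta-tubulin, Ncam1 (34.6) and Elavl3 (31.6) were the strongest. All 20 cell cycle genes and all 28 housekeeping genes were marked too, in each replicate's own list as well (exact test, adjusted p = 0.00121 and 4.91e-05), but CpG-matched genes reached 97.5% and 97.1% (adjusted p = 1.0 for both). Aurka (21.2), whose peak also covered the promoter of Cstf1, Rrm2 (15.1) and Plk1 (13.9) led the cell cycle list, and Actb (48.8), Ywhaz (41.1) and Eef2 (34.3) the housekeeping list.

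In 4 further lists marking was not past the threshold. Of 18 neurotransmitter genes 15 were marked, with the glycine transporter gene Slc6a5 (enrichment 17.3) and the GABA synthesis genes Gad2 (17.2) and Gad1 (16.3) the strongest, and with Tph2, Th and Dbh, all of monoamine synthesis, unmarked. Their adjusted p was 0.181, the same as for the 15 of 18 retinoic acid genes marked, led by Rxrb (23.0), whose peak also covered the promoter of Slc39a7, Rxra (19.9) and Rara (17.3), with Aldh1a1, Cyp26c1 and Rbp1 unmarked. The neurotransmitter list did pass with a window of 2000 bp (94.4%, exact test, adjusted p = 0.0163). Ddc, also of monoamine synthesis and named here outside the rule, was marked in the replicated list, although only replicate 2's own list marked it. Each replicate's own list marked 15 genes of both lists. Glial genes were marked in 12 of 18 cases (exact test, adjusted p = 1.0), with Slc1a2 (17.1) and the myelin genes Mbp (15.5) and Cnp (11.7) the strongest, and 3 other myelin genes, Mog, Mag and Plp1, unmarked. Midbrain and dopaminergic genes were marked in 9 of 12 cases (exact test, adjusted p = 0.862), with Nr4a2 (11.8), Pax3 (9.91) and Sall4 (9.2) the strongest and Foxa2, Aldh1a1 and Helt unmarked. The replicates' own lists marked 15 and 14 glial and 9 and 10 midbrain genes.

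Forebrain regulators, which are not used for hindbrain identity, were marked in 16 of 25 cases, 64.0% against 65.6% of other genes (Fisher's exact test, adjusted p = 0.87). Their promoters are CpG-rich, however, and 90.8% of CpG-matched genes were marked, so that against these the share was lower (permutation, adjusted p = 0.000173). This matched comparison used the replicated list alone, and whether it holds in each replicate's own list was not tested. The replicates differed here: replicate 1's own list marked 22 of the 25 genes and replicate 2's marked 15. With replicate 1's list alone the share was 88% and lay above other genes (exact test, adjusted p = 0.0483). Bcl11b (enrichment 25), Satb2 (9.76) and Lhx2 (9.48) were the strongest. Foxg1, the master regulator of the telencephalon, Nkx2-1 and Six3 were unmarked in the replicated list.

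Genes of blood cells, liver, germline and sensory receptors were seldom marked. Only 4 of 15 erythroid genes (Fisher's exact test, adjusted p = 0.00778), 3 of 16 microglia and macrophage genes (0.000536), 1 of 16 liver genes (7.72e-06) and 1 of 16 germline genes (7.72e-06) had a mark. The replicates' own lists marked 5 and 5 erythroid, 5 and 4 microglial, 4 and 3 liver and 1 and 2 germline genes. The marked members were weak, such as Epor and Tal1 (both 5.99) and Gypa (5.45) in the erythroid list, C1qc (3.21), Aif1 (3.07) and Tmem119 (2.35) in the microglial list, Trf (5.07) in the liver list, whose peak also covered the promoter of Gm20425, and Dazl (6.41) in the germline list. The globin genes Hba-a1, Hba-a2 and Hba-x, the microglial genes Csf1r, Cx3cr1 and P2ry12, the hepatocyte genes Alb, Apoa1 and Apoa2, and the germ cell genes Ddx4, Sycp1 and Sycp3 were unmarked in the replicated list. Of these, Cx3cr1 and Apoa2 had a peak in replicate 1's own list and Apoa1 in replicate 2's. Against CpG-matched genes the germline list stayed lower (6.25% against 71.6%, permutation, adjusted p = 0.000104), while the erythroid (0.641), microglial (1.0) and liver (0.197) lists no longer passed. With the pooled list the microglial share was 50% (exact test, adjusted p = 0.239). Of 1134 olfactory and 331 vomeronasal receptor genes 1 each was marked, Olfr94 and Vmn1r4, and the peak at Vmn1r4 also covered the promoter of Nt5c3. Olfr1416, Olfr1415 and Olfr1414, and Vmn1r1, Vmn2r1 and Vmn2r2, were the first unmarked members of these lists. The replicates' own lists marked 7 and 9 olfactory and 1 and 1 vomeronasal receptor genes. Both shares lay below those of CpG-matched genes, 9.45% and 5.08% (permutation, adjusted p = 0.000104 for both).

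Of the other cell types that the dissected tissue can hold, 5 lists were not past the threshold in marking. The counts were 8 of 16 endothelial genes (Fisher's exact test, adjusted p = 0.243), 12 of 17 genes of mesenchyme, meninges and mural cells (0.868), 9 of 12 choroid plexus genes (0.862), 13 of 14 neural crest and Schwann cell genes (0.0679) and 6 of 15 skeletal muscle genes (0.0773). The replicates' own lists marked 10 and 10 endothelial, 13 and 12 mesenchymal, 9 and 7 choroid plexus, 13 and 12 neural crest and 8 and 6 muscle genes. Skeletal muscle did pass with a window of 500 bp (33.3%, exact test, adjusted p = 0.0233), and neural crest when replicated peaks had to be covered to 50% in each replicate (0.04). Kdr (enrichment 12.5), Egfl7 (10.3) and Sox18 (6.61) were the strongest endothelial genes, and Pecam1, Cdh5 and Tek were unmarked. Foxc1 and Twist1 (both 7.67) and Pdgfrb (6.55) led the mesenchymal list, and Col3a1, Lum, Dcn, Rgs5 and Acta2 were unmarked. Enpp2 (8.50), Kl (7.86) and Foxj1 (6.69) led the choroid plexus list, where Ttr, Kcnj13 and Folr1 were unmarked. The strongest genes of the muscle list, Mylpf (28.3) and Actn3 (14.7), and of the neural crest list, Mpz (23.1), shared their peaks with the promoters of Tbc1d10b, Zdhhc24 and Sdhc. Tfap2a (19.4) and Eya1 (12.3) in the neural crest list and Pax7 (5.85) in the muscle list did not share their peaks with another protein-coding promoter. Plp1 was the unmarked member of the neural crest list, and Myog, Myf5 and Myf6 were among those of the muscle list.

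**Figure D3:**
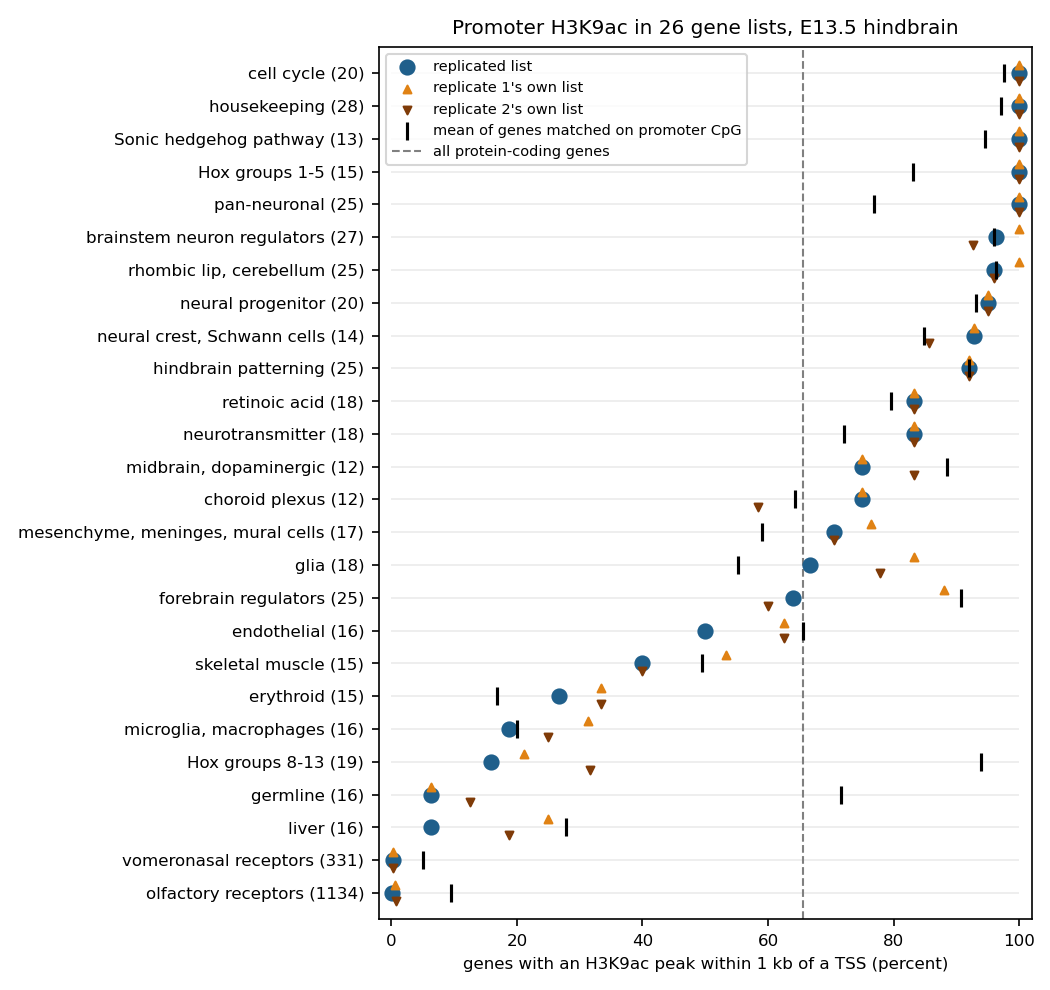
Percent of genes in each of 26 lists (number of genes in brackets) with an H3K9ac peak within 1 kb of a TSS, for the replicated list and each replicate's own list, with the mean of genes matched on promoter CpG content as a vertical tick and the 65.6% of all protein-coding genes as a dashed line. Groups 8 to 13 of the Hox genes lie far below their matched mean of 94.0%, and forebrain regulators are the list on which the replicates differ most in number, 22 against 15 genes.

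Breadth was high in several regulator lists and in housekeeping genes, and strength in housekeeping genes and, in some settings, the Hox genes of groups 1 to 5 and pan-neuronal genes. Among marked genes, 6 lists besides housekeeping had broad marks, while brainstem neuron regulators were not past the threshold (percentile 54.3, permutation, adjusted p = 0.686). The Hox genes of groups 1 to 5 had a median covered length of 9077 bp within 5 kb of the TSS, percentile 99.7 of all marked genes, against a median of 2314.5 bp over all of them. Covered length also counts peaks at neighbouring promoters. Hoxb3, Hoxb4 and Hoxb5 share 1 peak, so the number of Hox genes overstates the independent evidence here too. Hindbrain patterning genes had 6121 bp (percentile 96.5), progenitor genes 4786 bp (90.7), pan-neuronal genes 4492 bp (88.5), rhombic lip genes 3998 bp (84.2), housekeeping genes 3906 bp (83) and hedgehog pathway genes 3803 bp (81.6). The broadest members were Irx5 (9545 bp) and Meis2 (9860 bp) among patterning genes, Dll1 (7535 bp) and Hes5 (6944 bp, with the promoter of Pank4 under its TSS peak) among progenitor genes, and Myt1l (9450 bp) and Elavl2 (7427 bp) among pan-neuronal genes. In the housekeeping list they were Tubb5 (7143 bp) and Actb (6280 bp), and in the hedgehog list Ptch1 (9017 bp) and Sufu (4817 bp), whose TSS peak reached the promoter of Actr1a. The permutation test gave an adjusted p of 0.00011 for the first 4, which rests on the smallest p the resamples can give, 0.00044 for the rhombic lip and housekeeping lists and 0.026 for the hedgehog list. The hedgehog list did not pass without replicate 1 (permutation, adjusted p = 0.101) or within 2 kb of the TSS (0.437). Choroid plexus genes had a narrower mark than other genes (1167 bp, percentile 15, permutation, adjusted p = 0.0291), which did not hold with CpG matching (adjusted p = 0.106) nor on either replicate's own list (0.191 without replicate 1 and 0.0859 without replicate 2). Other lists passed only in some settings. Among them, in adjusted permutation tests, forebrain regulators were narrower within 2 kb of the TSS (p = 0.0116) and without replicate 2 (percentile 10.8, p = 9.6e-05). Microglial genes were narrower within 2 kb (percentile 3.24, permutation, adjusted p = 0.016), skeletal muscle genes without replicate 2 (9.56, p = 0.00315) and Hox groups 8 to 13 without replicate 1 (2.96, p = 0.00016). Retinoic acid genes were broader within 2 kb (percentile 84, permutation, adjusted p = 0.00719), without replicate 2 (80.2, p = 0.0149) and with peaks covered to 50% in each replicate (77.7, p = 0.0452).

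In the lists not past the threshold in breadth, the broadest members included Gata3 (8376 bp) among brainstem regulators, Slc6a5 (9631 bp) among neurotransmitter genes, Rara (8439 bp) in the retinoic acid list, and Hoxb8 (8635 bp) and Hoxb9 (3240 bp) of Hox groups 8 to 13. Bcl11b (7824 bp) and Lhx2 (7343 bp) were the broadest forebrain regulators, Slc1a2 (6678 bp) and Pdgfra (3750 bp) the broadest glial genes, and Nr4a2 (6289 bp) and Pax3 (5906 bp) the broadest midbrain genes. In the cell cycle list they were Mcm7 (4589 bp), whose TSS peak reached the promoter of Ap4m1, and Plk1 (4048 bp). In the erythroid list they were Tal1 (6008 bp) and Epor (2213 bp), in the endothelial list Egfl7 (4444 bp) and Esam (2630 bp), and in the mesenchymal list Foxc1 (4699 bp) and Foxc2 (3019 bp). In the choroid plexus list, which was past it, they were Foxj1 (4821 bp) and Enpp2 (2192 bp). Tfap2a (8750 bp) and Tfap2b (6548 bp) were the broadest neural crest genes, Mylpf (4168 bp) and Pax7 (3693 bp) the broadest muscle genes, and Aif1 (1484 bp) and C1qc (1098 bp) the broadest microglial genes.

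In strength by enrichment, housekeeping genes lay above other marked genes, at a median enrichment of 24.5 (percentile 85.1, permutation, adjusted p = 0.00011). The patterning, progenitor, hedgehog, pan-neuronal and low-group Hox lists were not past the threshold in strength, with median percentiles of 48.9, 47.5, 62.2, 65.6 and 65.7. The 3 marked genes of Hox groups 8 to 13 were not either (percentile 8.99, permutation, adjusted p = 0.0607), but passed as weaker without replicate 1 (0.0009), without replicate 2 (0.022) and with CpG matching (0.0037). The Hox list of groups 1 to 5 did pass on each replicate's own list, at percentiles 82.6 and 81.6, with -log10 p in place of enrichment (percentile 77.1, permutation, adjusted p = 0.0269), and matched on CpG (0.0299), and the pan-neuronal list when matched on CpG (adjusted p = 0.0037). In total 15 lists had weaker promoters than other marked genes, among them forebrain regulators (median enrichment 4.16, percentile 5.72), glia (4.31, percentile 6.19) and brainstem neuron regulators (4.59, percentile 7), each with an adjusted p of 0.00011. Rhombic lip genes were broad and weak at once, at percentile 22.8 of strength (permutation, adjusted p = 0.00684), a call lost when replicated peaks had to be covered to 50% in each replicate (0.0517). In the permutation test the call was lost for neurotransmitter (adjusted p = 0.0502), erythroid (0.632) and microglial genes (0.385) with CpG matching. It was also lost for retinoic acid genes on each replicate's own list (0.0707 without replicate 1 and 0.0582 without replicate 2), and for the erythroid (0.0595) and choroid plexus lists (0.0621) without replicate 1.

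**Figure D4:**
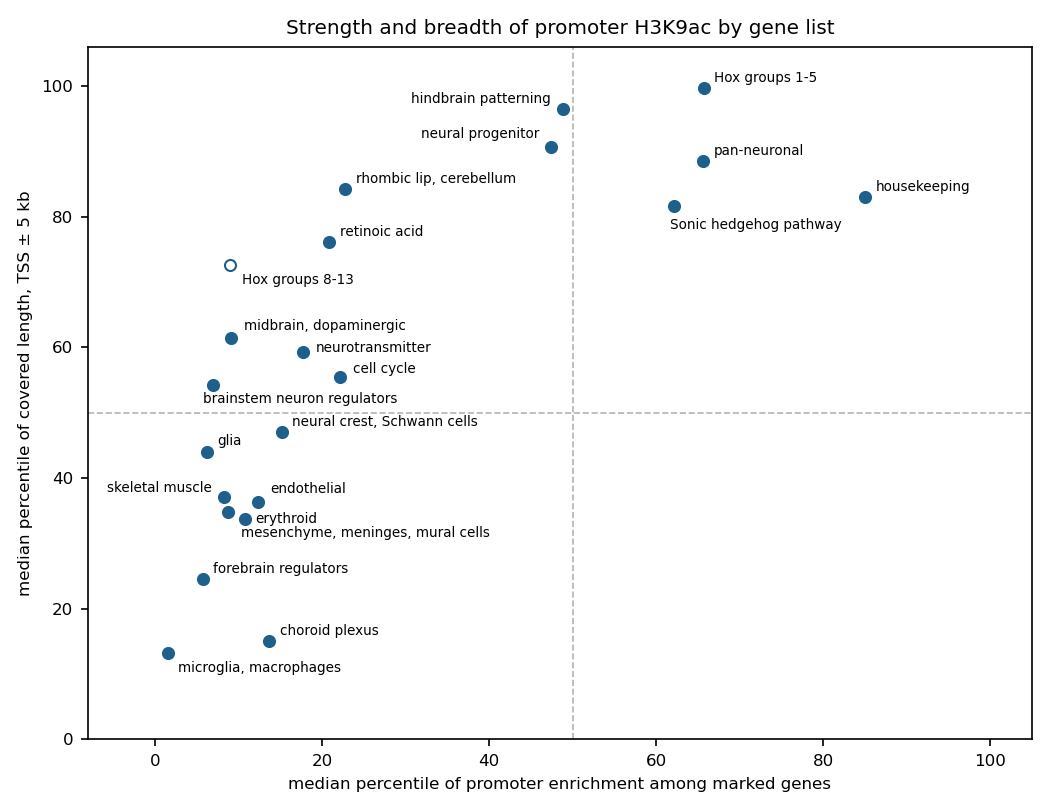
Median percentile of covered length within 5 kb of the TSS (vertical axis) against median percentile of promoter enrichment (horizontal axis), each among all marked genes, for the 22 lists with at least 3 marked members. Filled points had an adjusted p below 0.05 on at least 1 axis and dashed lines mark the 50th percentile. Hox groups 1 to 5 lie highest in breadth (99.7) and housekeeping genes farthest right in strength (85.1).

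Away from promoters, the replicated list held 26361 distal peaks (50.6%), with a median enrichment of 3.35, and 8379 protein-coding genes had at least 1 assigned. Hindbrain patterning genes had 8.12 distal peaks per gene, 3.77 times the 2.15 of genes with territories of like length (permutation, adjusted p = 0.00052). Pan-neuronal genes had 5.60 per gene against 1.86 (permutation, adjusted p = 0.0146), which did not pass on replicate 1's own list (ratio 2.27, adjusted p = 0.0506, without replicate 2). Progenitor genes (4.95 against 1.93, permutation, adjusted p = 0.0776) and rhombic lip genes (5.28 against 2.28, adjusted p = 0.0776) did not pass. The rhombic lip list passed when peaks were limited to 100 kb of the TSS (permutation, adjusted p = 0.0367). Hox groups 1 to 5 had 0.933 distal peaks per gene against 0.562 (permutation, adjusted p = 0.524). Forebrain regulators had 2.32 against 1.93 (permutation, adjusted p = 0.746). Olfactory and vomeronasal receptors had 0.0309 and 0.0242 per gene (permutation, adjusted p = 0.00026 for both).

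Gene by gene, 11 promoters were covered over the full 10001 bp. They were Hoxb3, Hoxb4, Hoxb5 and Hoxb6, the LIM-homeodomain genes Lhx1, Lhx5 and Lmx1b, the transcription factor Ebf3, Cyp26b1, which breaks down retinoic acid, Nrn1, and Slc32a1, which loads GABA and glycine into vesicles. The peak at Lhx1 (chromosome 11, 84518308 to 84534780) was 16473 bp wide, and that at Lmx1b (chromosome 2, 33633255 to 33645839) 12585 bp. Each of these genes was covered over at least 9090 bp in both replicates' own lists, where Cyp26b1 had 9521 and 9090 bp. Cyp26b1 combined this breadth with an enrichment of 8.55, percentile 20.9. The strongest promoters were those of Marcksl1 (enrichment 49.1, chromosome 4, 129513310 to 129515218), Actb (48.8), Mex3b (47.7), Dbn1 (47.4), Adnp (47.1), Actg1 (46.3), Arid1a (45.6), Skida1 (45), Tnrc18 (44.9) and Kmt5b (44.7). Marcksl1, Dbn1 and the actin genes encode cytoskeletal proteins or their partners, and Adnp, Arid1a and Kmt5b encode chromatin regulators. The most distal peaks were assigned to Gse1 (77), Camta1 (65), Zfhx3 (51), Zmiz1 (49) and Ccdc182 (47).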

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

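Peaks on sequences outside chromosomes 1 to 19, X and Y took no part in the comparisons of the report. The replicated list held 11 peaks there, on 5 unplaced or unlocalised contigs, more than the 3 that a count of 0 would allow, which does not tell whether the number is unusual. The pooled list held 14, replicate 1's list 13 and replicate 2's list 15, and the highest enrichment among the replicated ones was 11.8. No explanation for them was tested.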

How the results depend on the processing

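The restriction to replicated peaks covered to 50% in each replicate was chosen only after the data were seen. Over the summary results, 49 values under the settings fixed before the data were seen and 5 under the added one kept their direction and their side of the threshold, or for counts stayed within 1.5 times the main count. The exceptions were 2. The rank correlation rose from 0.816 to 0.836 with -log10 p in place of enrichment, outside its interval. That interval takes peaks as independent and is too narrow to judge the change. The number of lists past the threshold in marking fell from 16 to 6 when genes were matched on promoter CpG, which by its construction sets each list against genes of like CpG content.

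List by list, 12 values under the earlier settings and 2 under the added one changed direction. The marked share of forebrain regulators, just below that of other genes in the main setting, lay above it with a window of 2000 bp (68%) and in the pooled list (80%), and ran from 60% without replicate 1 to 88% without replicate 2, of these 4 past the threshold only in the last. Glia changed side with a window of 500 bp (61.1%) and with 1 TSS per gene (55.6%). Choroid plexus genes did so with 1 TSS per gene (58.3%) and in the restricted list (58.3%), and ran from 58.3% without replicate 1 to 75% without replicate 2. Mesenchymal genes did so in the restricted list (64.7%). With CpG matching the direction changed, at unchanged shares, for rhombic lip (96%), midbrain (75%) and erythroid genes (26.7%). The breadth percentile of Hox groups 8 to 13 was 72.5 over its 3 marked genes but 2.96 without replicate 1 and 30.9 without replicate 2, where 6 and 4 members counted as marked. For the other changes the cause was not tested.

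Of the earlier settings' values per list, 325 kept direction and side of the threshold, 24 lost the threshold and 18 gained it; of the added ones, 57 kept both, 2 lost it and 2 gained it. For strength, breadth and distal peaks these counts cover only lists past the threshold in the main or any alternative setting, a limit set after the changes of direction were first seen; lists past it nowhere were not followed one by one. No paired analysis was possible because there was 1 group. Depth is unknown, so its effect on the number of weak peaks could not be measured.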

Other observations

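The 2 tests on replicated peaks without coverage in both replicates and the test in 1-Mb windows of chromosome X were chosen only after the result was seen, and the peaks and genes named in the next paragraph were chosen after their values were seen.

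Some of the strongest and broadest peaks lay at non-coding genes. The highest enrichment in the whole replicated list, 53.1, was on chromosome 7 (73556326 to 73558612), with its summit 68 bp from a TSS of the non-coding gene 1810026B05Rik and 16295 bp from that of the nearest protein-coding gene, Chd2. A peak of 10400 bp on chromosome 13 (83724059 to 83734458, enrichment 45.6) had its summit 1197 bp from a TSS of the long non-coding RNA Gm26803, and 155102 bp from the nearest coding gene TSS, at Mef2c. A peak of 14459 bp on chromosome 7 (79498898 to 79513356, enrichment 34.7) lay 108 bp from a TSS of Mir9-3hg, the host gene of a microRNA of neural progenitors. Among distal peaks, over 2.5 kb from any annotated TSS, the strongest was on chromosome 17 (46855407 to 46859302, enrichment 42.4), 25045 bp from the TSS of Bicral. Only 1 group was studied, so no explanation that needs a second condition could be tested for the patterns below.

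Forebrain regulators were marked in replicate 1 and not in replicate 2 in 7 cases (Dlx1, Lhx8, Foxg1, Nkx2-1, Rax, Vax1 and Emx2) and the other way round in 0. The longer list of replicate 1 is argued against: with the 92736 strongest peaks of each replicate the excess was still 6. Forebrain cells carried along in replicate 1's dissection remain a candidate explanation that these data cannot decide. Distal peaks near all 25 genes of the list were 153 in replicate 1 and 99 in replicate 2. That ratio was 1.3 times that of other genes (95% bootstrap interval over genes 1.09 to 1.70), as this explanation would have it. The 25 genes include the 7 above and each replicate is 1 library, so the ratio is not independent support. Its interval covers the spread between genes, not between dissections. Chance remains open too, as the split of 7 against 0 compared with that of the other genes gave p = 0.0511 and an adjusted p of 1.0 over the 26 lists (Fisher's exact test). The peaks were weak, with enrichments of 2.58 to 4.22 in replicate 1, against a median of 14.8 over its marked genes.

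The replicated list held 9464 peaks (18.2%) that were not covered to at least 50% of either interval by a peak of each replicate. Of these, 6325 met that condition in replicate 1 alone, 2779 in replicate 2 alone and 360 in neither. A mere difference of overlap rule is argued against, as 3.29% of them overlapped a peak of each replicate by even 1 bp. Their median enrichment was 3.05, below the lower quartile of 3.35 of the other replicated peaks, as peaks near the calling threshold would have it. Peaks picked for lacking coverage in a replicate are apt to be weak, so this value cannot decide whether that threshold explains them. Promoters held 7.96% of them against 40.1% of the others, and how they entered the list is not given in the sources used here.

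Chromosome X had 281 unreplicated pooled peaks, 1.72 per Mb where the autosomes had 16.6 to 54.3, and 75.2% of its pooled peaks were in the replicated list, against 40.7% to 45.6%. A lower density of coding promoters is argued against, since the regression over 19 autosomes predicts 19.7 per Mb with a 95% prediction interval of 7.16 to 32.2. The regression on GC, written down first, had X inside its interval (-10.4 to 8.11) as low GC would have it, but it decides little, as X's GC of 39.3% lies below that of every autosome (40.5% to 43.8%). Low GC is argued against as the whole cause only by the later windows, where X held 1.83 such peaks per Mb and autosomal windows matched on GC 7.01 (central 95% of draws 6.06 to 8.01), itself below every autosome's mean. Lower read coverage of X, of which males have a single copy, remains a candidate explanation, although the tissue was pooled from males and females. Replicated peaks were also fewer than coding promoters predict (5.21 per Mb against 14.8, interval 6.62 to 23). They lay just below the range of GC-matched windows too (5.58 against 6.58, central 95% of draws 5.66 to 7.61), a smaller gap than for unreplicated peaks. Marked CpG-rich promoters had a median enrichment of 10.2 on X against 18 on autosomes, while the median over all replicated peaks was higher on X (6.13 against 3.78). On X the pooled list held 1132 peaks, fewer than replicate 1's 1181 and replicate 2's 1199. On each autosome it was longer than either replicate's list. Coverage itself was not measured.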
